A study of Mus musculus with 6 samples.

How the data were processed

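RNA sequencing libraries from a mouse aortic endothelial cell line were compared. Per the labels, the line had been immortalised with an SV40 gene under doxycycline control, was expanded with doxycycline and was moved to medium without it. The labels give 3 genotypes: the parental line (WT), a line in which the gene of the splicing repressor Ptbp1 had been disrupted by CRISPR (KO), and that line with a human PTBP1 cDNA added back (Rescue). Each genotype had 1 library without TNF and 1 library from cells given TNF at 30 ng/mL, so 6 libraries fell into 6 groups with 1 library per group and no replicates. Libraries were made from RNA with a SMARTER kit for messenger RNA per the labels' protocols, and strand was not given in the sources used here.

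For each library the authors deposited RSEM expected counts and TPM values per gene. RSEM is named in the submitters' processing notes, and its version, the aligner and the genome build were not given in the sources used here. For the library labelled Rescue the deposited expected counts and TPM were per transcript and were summed to genes. The authors also deposited a second quantification of estimated counts per gene, a percent-spliced-in value (psi, a fraction from 0 to 1) with the number of estimated reads behind it for each splicing node, and counts of reads per splice junction, each described per the file headers. The tool behind these 3 kinds of files was not given in the sources used here. A node is a part of a gene between neighbouring splice sites. Types used were cassette exon parts (CE), alternative acceptor (AA), alternative donor (AD) and retained intron (RI). Of 86140 CE nodes, 99.9% shared an exon edge with GENCODE vM21, so the coordinates are GRCm38 and the annotation of nodes was taken from that release. Deposited counts per transcript of the second quantification were not used here.

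Libraries were grouped by their labels. Before the data were examined, it was seen that the names of the deposited files read another group than the label for 4 of 6 libraries. File names read basal, KO or rescue, each with or without TNF. Basal was taken here to mean the parental line (WT), which the file names do not state. On that reading, the library labelled KO has files named WT with TNF, and the one labelled Rescue has files named KO. The one labelled WT_TNF has files named KO with TNF, and the one labelled KO_TNF has files named rescue. The libraries labelled WT and Rescue_TNF have files that read as labelled. Every result was therefore computed with the labels' groups, as the main result, and with the groups that the file names read, as a second grouping fixed in advance, with both to be printed if Ptbp1 or TNF target genes went against a label. In the text, "labelled" refers to the labels and "named" to the file names, with basal read as WT. The libraries named WT are those labelled WT and KO, those named KO are labelled Rescue and WT_TNF, and those named rescue are labelled KO_TNF and Rescue_TNF. Libraries named TNF are those labelled KO, WT_TNF and Rescue_TNF. The comparisons, tests, thresholds, gene lists, rules for named genes and other settings were all fixed before the data were examined, and additions made later are named as such.

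Expected counts were rounded to whole numbers. Of 21675 genes, 12729 passed edgeR's filterByExpr. Genes were tested with edgeR's quasi-likelihood test with TMM factors in an additive model of genotype and TNF over all 6 libraries, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. This model leaves 2 residual degrees of freedom, which are the differences of an effect between levels of the other factor. Its p-values hence set an effect against how unequal it was across genotypes or treatments, not against a spread between replicate cultures. The 4 comparisons were TNF over the 3 genotypes, KO against WT, Rescue against KO and Rescue against WT. A model in which the TNF response of KO had its own term against WT and Rescue together was added after seeing the data and leaves 1 residual degree of freedom. That residual is the difference of the TNF response between WT and Rescue. Its p-values hence treat these genotypes as if they were replicates of each other. Levels of genes are CPM scaled by the TMM factors, except that levels given with an interval, those of Ptbp3, of cell type markers in the marker paragraph, of Xist and of Ifit1 are unscaled CPM. Fold changes are on the log2 scale. The value after ±, called SE, is the fold change divided by the square root of the quasi-likelihood F. It restates the test and was not estimated separately as a standard error. For genes near 0 CPM in 1 genotype, such as Cd34, it can be smaller than the counting error. Ratios of single libraries used a prior count of 2 and carry no test.

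Gene lists were tested with limma's camera with an inter-gene correlation of 0.01 on voom values, with an estimated correlation and fry as alternatives, adjusted over 15 lists per comparison. These lists were TNF and NF-kB targets, TNF receptor signalling components, interferon response, DNA replication and mitosis, p53 targets, unfolded protein response, cholesterol synthesis, extracellular matrix and integrins, shear-responsive and YAP-linked genes, splicing regulators, and markers of endothelial, smooth muscle and fibroblast, blood, epithelial and neuronal cells. Counts of members past the threshold are over all genes tested, and a second count is adjusted over the list alone. A further list held 40 genes with splicing events regulated by PTBP1, of which 39 were found. For medians of lists in single libraries, a 95% bootstrap interval over members and the percentile among 10000 random lists of equal size matched on expression describe these libraries only.

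Nodes of the 4 types were tested with limma on logit psi in the same additive model. Tested were the 28664 nodes with at least 20 reads in all 6 libraries and a psi that was not identical in all of them. They were called at an adjusted p under 0.05 and a mean psi difference of at least 0.1. On simulated data this fit recovered 0% of nodes changed by 0.4, so its count of 0 says nothing about real changes. A fit weighted by reads and by pooled psi, over 12519 nodes with a pooled psi of 0.02 to 0.98, was therefore added after the simulation. It recovered 50% of 200 nodes changed by 0.4 in KO against WT and 77% for TNF, and 0% and 0.5% of those changed by 0.2. In simulated counts for the 12583 genes tested in KO against WT, the gene test recovered 95.5% of 200 genes changed by 2-fold, and 100% of those changed by 4-fold among 12563. Of its calls in these simulations, 5.4% and 5.2% had not been changed. For TNF, 99.5% of 200 genes changed by 2-fold were recovered among 12569 tested, and for Rescue against KO 93.5% among 12560. All simulations used the groups that the file names read and effects that were equal at every level of the other factor. Simulated gene counts had a common dispersion for all genes. Simulated nodes likewise had a common spread beyond counting error, and their psi was only raised, never lowered. The recovery hence does not apply to the labels' groups or to genes whose TNF response differed between genotypes.

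The named genes are the 8 with the largest rise and the 8 with the largest fall past the threshold per comparison, with a mean of at least 5 CPM and the same direction at every level of the other factor. Where none passed, 4 each way were taken and are said to have missed the threshold. Added to these were Ptbp1 to Ptbp3, 10 further genes fixed in advance and the 4 members of each list with the largest change. Named nodes are the 6 largest called each way with 1 node per gene, and the largest per gene of the splicing list. Not all of them are printed. Shares of junction reads carry exact Clopper-Pearson 95% intervals, counts carry exact Poisson intervals, and a count of 0 is given with the share that 3 reads would make. The intervals cover counting error only. Junction shares were compared by Fisher's exact tests on pooled reads, which compare those libraries and not the conditions.

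Alternatives were RLE size factors, DESeq2, no filter on low counts, at least 10 counts in every library, the second quantification, a prior count of 0.5, other read minimums of 10 and 50, CE nodes only, untransformed psi, a psi difference of 0.2, and leaving out each library in turn. A count within 1.5 times of the main count was taken as unmoved, as was a median or slope within the main value's bootstrap interval. A gene was taken as reversed where its sign changed and either value passed the threshold. Depth was even, with 19598773 to 21626838 RSEM counts per library. No 2 libraries had identical counts. The median log2 fold change of all genes lay within 0.031 of 0 in every setting. The 2 quantifications matched library by library, with a correlation across genes of residual log2 CPM of 0.965 to 0.977 for files of one sample and at most 0.485 for files of different samples, genes not being independent replicates. Thus both gene count files of 1 sample hold 1 library. The psi and junction files were not matched in this way. RSEM used mouse RefSeq transcripts, and reads of the human PTBP1 cDNA could not be separated here from mouse Ptbp1. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.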

Results

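Ptbp1 binds pyrimidine-rich RNA and mostly represses exons, and it also shuts down its neuronal paralogue Ptbp2 by keeping a 34-nt exon of Ptbp2 out of the messenger RNA. Loss of Ptbp1 therefore raises Ptbp2, which makes Ptbp2 a reporter of Ptbp1 activity. TNF is a cytokine that turns on adhesion molecules such as Vcam1 and Icam1 and chemokines such as Ccl2 through NF-kB. Both readouts went against the labels. Ptbp2 was at 216.4 CPM (95% counting interval 210.0 to 222.8) in the library labelled Rescue and 185.4 (179.5 to 191.4) in the library labelled WT_TNF, against 38.3 (35.6 to 41.2) in the one labelled WT, 36.6 (34.1 to 39.3) in the one labelled KO, 70.3 (66.8 to 74.0) in the one labelled KO_TNF and 78.8 (74.9 to 82.9) in the one labelled Rescue_TNF. Ccl2 was at 2036.92 CPM in the library labelled KO, which should not have had TNF, and at 50.32 CPM in the one labelled KO_TNF. Results with the groups that the file names read are therefore given beside those with the labels' groups in each comparison.

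Ptbp1 itself was at 339.3 CPM (331.2 to 347.6) in the library labelled WT, 409.4 (400.9 to 418.1) in that labelled KO, 383.7 (375.2 to 392.2) in that labelled Rescue, 410.3 (401.5 to 419.1) in that labelled WT_TNF, 180.4 (174.8 to 186.2) in that labelled KO_TNF and 192.1 (186.0 to 198.3) in that labelled Rescue_TNF. Deposited TPM values of Ptbp1 were 236.2, 270.2, 265.8, 275.1, 126.6 and 128.9 in the same order. Messenger RNA of Ptbp1 thus persisted in every library, as it can where CRISPR changes a coding sequence without destroying the transcript. Reads across 2 junctions of Ptbp1 differed between the libraries as well, and they are taken up after the comparisons. Ptbp3, a further paralogue, ranged from 73.8 CPM in the library labelled WT to 115.0 in the one labelled Rescue_TNF.

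**Figure D1:**
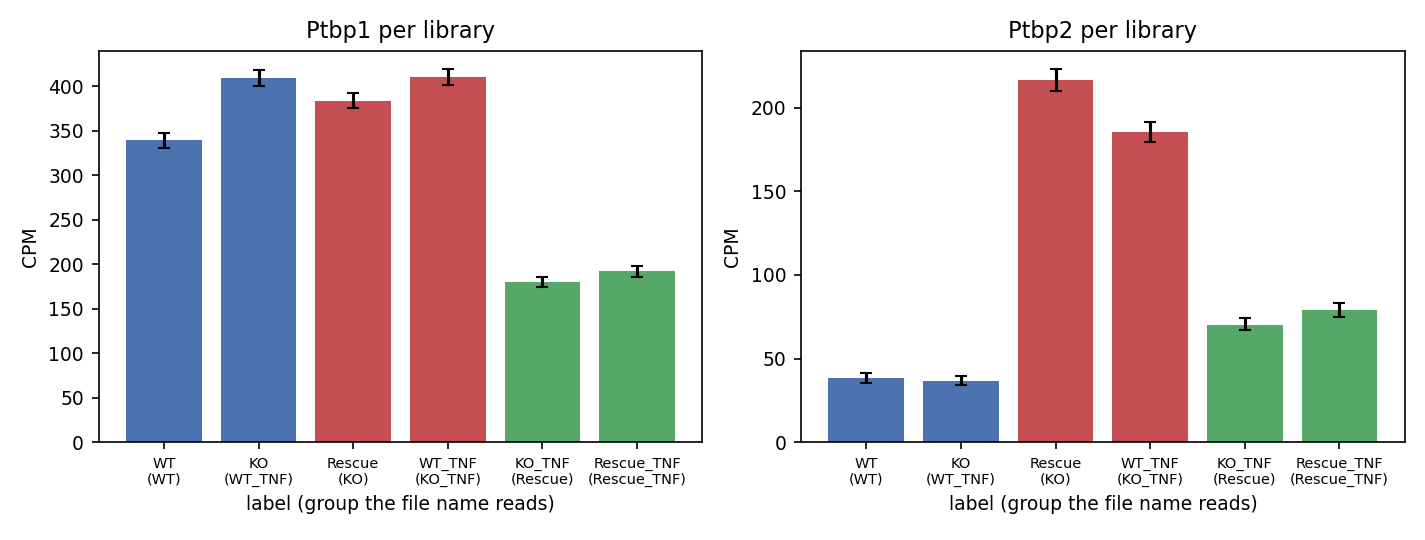
Ptbp1 and Ptbp2 in each library in CPM with counting intervals. Ptbp2 was highest in the libraries labelled Rescue (216.4) and WT_TNF (185.4).

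**Figure D2:**
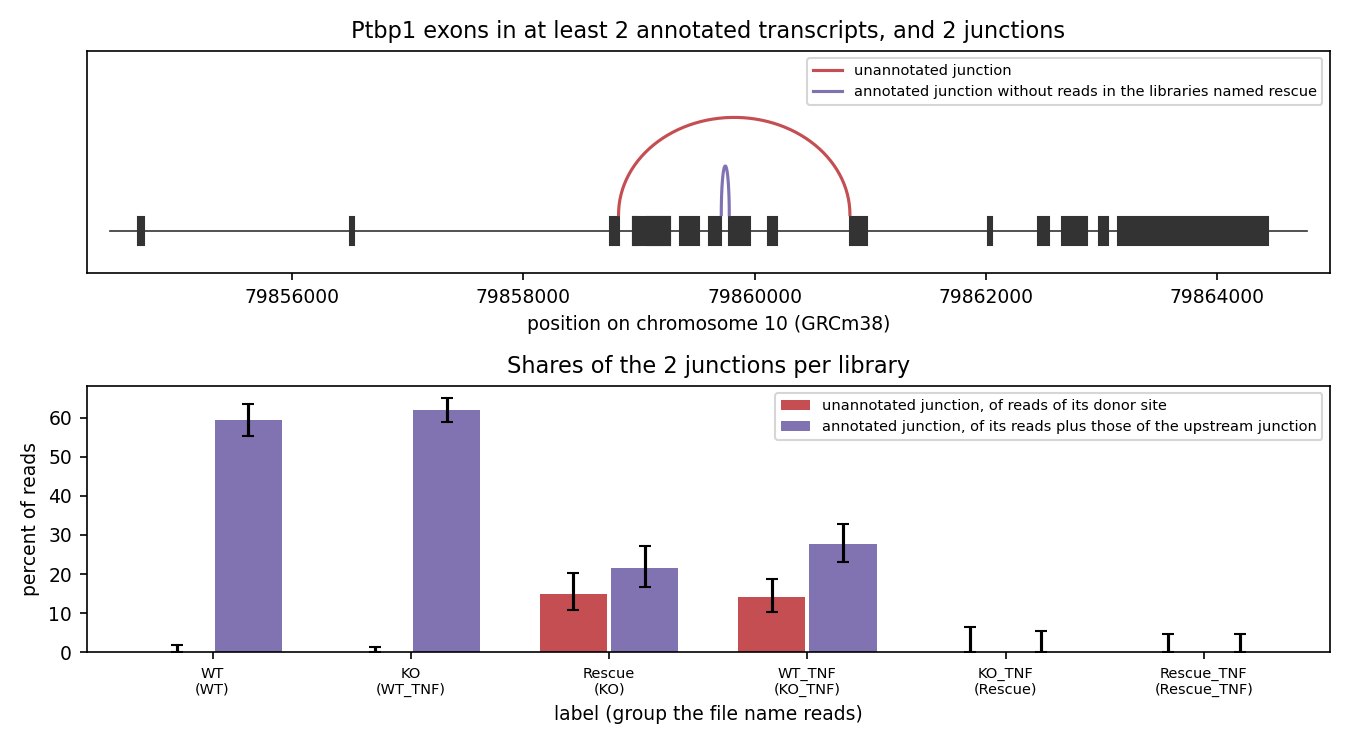
Ptbp1 junction shares in each library; the unannotated junction made up 15.0% in the library labelled Rescue and 14.19% in that labelled WT_TNF, and 0 in the others.

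TNF raises leukocyte adhesion molecules, chemokines and NF-kB's own inhibitors such as Nfkbia and Tnfaip3 in endothelial cells. With the labels' groups no such response was seen over the 3 genotypes. Ccl2 changed by 2.47 ± 2.96 (SE), Icam1 by 1.02 and Vcam1 by 0.65, all with an adjusted p of 0.999. The genes with the largest changes missed the threshold at the same adjusted p of 0.999. They were Nkd2 (4.05), a Wnt antagonist, the imprinted gene Peg3 (2.69), Olfm1 (2.24) and Cd300lb (2.00) among the higher, and Thy1 (-7.41), Nynrin (-6.39) and Cd34 (-6.23) among the lower. Ptbp1 changed by -0.68 and Ptbp2 by 0.59. By edgeR 0 of 12729 genes passed, with 491 at an unadjusted p under 0.05, and DESeq2 called 98 (9 up, 89 down). Leaving out any library left edgeR's count at 0. TNF and NF-kB targets had a median of 0.20 and a mean of 0.34 while the test pointed down (adjusted p = 0.522), and 0 of 36 members passed. DNA replication and mitosis genes had a median of 0.62 (camera adjusted p = 3.7e-11, adjusted p = 0.844 with an estimated correlation), with 0 of 30 members past the threshold. Interferon genes (median -0.95, camera adjusted p = 0.0058) and splicing regulators (median 0.19, camera adjusted p = 0.00488) were likewise lost, at an adjusted p = 0.844 with an estimated correlation.

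With the groups that the file names read, the TNF targets rose. Ccl2, which draws monocytes, rose by 4.69 ± 0.44 (adjusted p = 0.00871), and the adhesion molecules Icam1 (4.58 ± 0.47), Vcam1 (3.21 ± 0.34) and Sele (3.01 ± 0.41) rose with it. Feedback inhibitors of NF-kB rose as well, with Tnfaip3 at 2.32, Nfkbia at 2.20 and Tnip3 at 6.02 (adjusted p = 0.00735), as did the neutrophil chemokine Cxcl1 (1.85). Of the 36 tested members of the TNF and NF-kB target list 30 rose, 0 fell and 6 did not pass (35 rose when adjusted over the list alone), with a median of 2.03 (camera adjusted p = 3.1e-16, adjusted p = 0.599 with an estimated correlation). Among the genes with the largest rises, Nos2, which makes nitric oxide, went from 0.25, 0 and 0 CPM in the libraries labelled WT, Rescue and KO_TNF to 150.19, 0.20 and 26.98 in those labelled KO, WT_TNF and Rescue_TNF. Saa3, an acute-phase protein, had 0 CPM in the first 3 and 105.54, 0.25 and 5.15 in the last 3. Irg1, whose enzyme makes itaconate, had 0 in the first 3 and 45.23, 0.20 and 8.07. Complement genes C3 (5.95) and Cfb (6.50), the oxysterol enzyme Ch25h (6.93) and the chemokine Ccl8 (6.42) rose too.

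The largest falls included 4 small leucine-rich proteoglycans of the matrix, Aspn (-4.39), Fmod (-4.16), Prelp (-3.27) and Ogn (-3.09), while Dcn, of the same family, rose by 4.18. Aoc3 (-3.54), the Wnt modulator Sfrp2 (-3.42), Sned1 (-3.15) and Lrrc17 (-2.96) fell with them. Matrix-degrading enzymes Mmp13 (6.30), Mmp3 (4.42) and Mmp9 (4.12) rose, while fibronectin, Fn1, fell by 0.54 (adjusted p = 0.0425). Of 29 extracellular matrix and integrin genes 13 rose and 5 fell (14 and 7 when adjusted over the list alone), median 0.48 (camera adjusted p = 0.0298, adjusted p = 0.599 with an estimated correlation). Smooth muscle and fibroblast markers had 1 rise and 11 falls of 21 (2 and 12 over the list alone), among them Lmod1 (-1.16), median -0.73 (camera adjusted p = 0.0102, adjusted p = 0.599 with an estimated correlation). Interferon response genes had a median of 2.02 (camera adjusted p = 1.6e-06, adjusted p = 0.599 with an estimated correlation) although only 5 of 34 rose (4 over the list alone), such as Cxcl10 (3.92), Cxcl9 (5.58) and Cxcl11 (5.46). Gbp5 (3.79, adjusted p = 0.108) did not pass.

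Among 26 TNF receptor signalling components 8 rose and 0 fell (9 and 0 over the list alone), with the necroptosis gene Mlkl at 1.03 and Cflar at 0.59, median 0.14 (camera adjusted p = 0.0133, adjusted p = 0.599 with an estimated correlation). Splicing regulators had 5 rises and 0 falls of 37 (3 and 0 over the list alone), including Celf1 (0.38) and Raver1 (0.35), median 0.12 (camera adjusted p = 0.0133, adjusted p = 0.599 with an estimated correlation), and Ptbp1 (0.19), Ptbp2 (-0.01) and Ptbp3 (0.27) did not pass. Of 23 p53 targets 7 rose and 2 fell (7 and 2 over the list alone), with Fas at 1.55, Mdm2 at 0.85 and Sesn1 at -0.83, median 0.21 (camera adjusted p = 0.0412, adjusted p = 0.639 with an estimated correlation). Unfolded protein response genes had 0 rises and 5 falls of 18 (1 and 10 over the list alone), led by Trib3 (-1.23), Chac1 (-0.76) and Ddit3 (-0.68), median -0.21 (camera adjusted p = 0.0412, adjusted p = 0.599 with an estimated correlation). In cholesterol synthesis 1 of 17 fell, Dhcr7 (-0.48), and 0 rose (0 and 0 over the list alone), median -0.18 (camera adjusted p = 0.0412, adjusted p = 0.642 with an estimated correlation). Shear-responsive and YAP-linked genes had 4 rises and 5 falls of 17 (5 and 8 over the list alone), among them Bmp4 (-2.41), Angpt2 (-1.71), Edn1 (-1.59) and Amotl2 (-1.06), median -0.27 (camera adjusted p = 0.315).

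Lists without a result by camera were endothelial markers (2 rises and 0 falls of 14 tested, 1 and 0 over the list alone, Ecscr 3.84 and Flt1 0.96, adjusted p = 0.0783), DNA replication and mitosis (0 and 0 of 30, the same over the list alone, adjusted p = 0.154), blood cell and macrophage markers (2 and 1 of 5, the same over the list alone, adjusted p = 0.286), epithelial markers (0 and 1 of 3, the same over the list alone, adjusted p = 0.303) and neuronal genes (0 and 3 of 14, 1 and 3 over the list alone, adjusted p = 0.365). Over all genes 2802 passed (1427 up, 1375 down) by edgeR and 2749 by DESeq2. Leaving out the library labelled KO_TNF or that labelled Rescue_TNF left 3 calls, and leaving out that labelled WT or KO left 931 or 903. The p-values of this model rest on 2 residual degrees of freedom, and the intervals and p-values do not cover the spread between replicate cultures because there are no replicates.

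**Figure D3:**
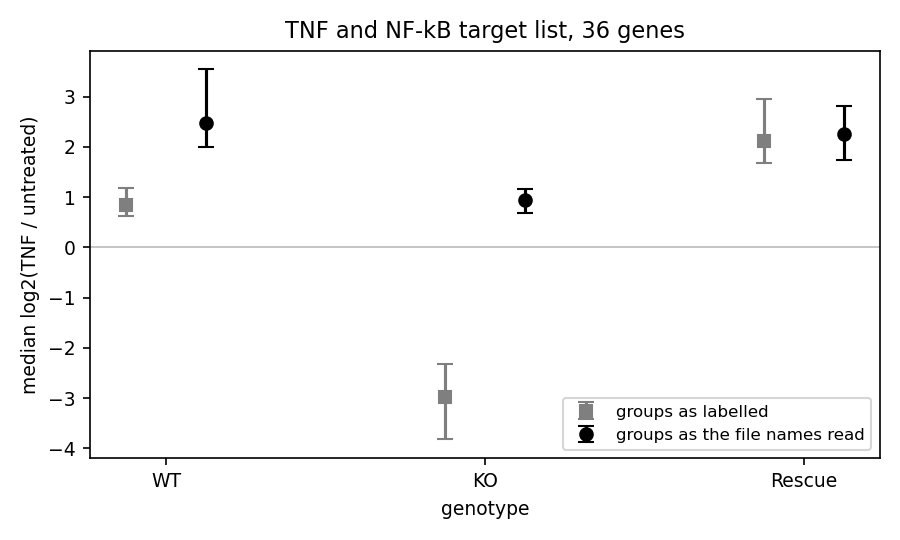
TNF response of TNF and NF-kB targets within each pair of libraries, as labelled and as named; the medians were 2.48, 0.94 and 2.26 in the pairs named WT, KO and rescue.

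The TNF response was smaller in the pair of libraries named KO (labelled Rescue and WT_TNF) than in the other pairs. The chemokines Ccl5 and Ccl2, the NF-kB inhibitor Nfkbia and the adhesion molecule Vcam1 belong to the genes whose response differed. Single-library medians of the TNF targets were 2.48 (bootstrap interval over genes 1.99 to 3.55) in the pair named WT, 0.94 (0.69 to 1.17) in that named KO and 2.26 (1.75 to 2.83) in that named rescue. KO minus WT was -0.18 (-0.36 to 0.04) in the untreated libraries and -1.71 (-2.25 to -1.47) in those given TNF. The difference of the responses, KO minus WT, was -1.54 (-1.81 to -1.13), and Rescue minus KO was 1.40 (0.87 to 1.47). In the model added after the data were seen, the response of KO was lower than in WT and Rescue for Ccl5 (-6.51), Gbp5 (-6.30), Vcam1 (-1.46), Nfkbia (-1.73), Ccl2 (-1.72) and Tnfaip3 (-1.70). As labelled, the medians were 0.84 (0.62 to 1.18) in the pair labelled WT, -2.98 (-3.82 to -2.32) in that labelled KO and 2.12 (1.68 to 2.96) in that labelled Rescue. Each pair is 1 library against 1, so these medians describe the libraries.

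Interferon response genes, which curb viruses, had medians of 3.77 (3.10 to 4.21), 0.25 (0.14 to 0.41) and 2.45 (1.43 to 2.71) in the pairs named WT, KO and rescue. They were already high in the untreated library named KO, with KO minus WT at 2.34 (1.95 to 3.41). Across 12729 genes the TNF responses correlated at 0.812 between the pairs named WT and rescue, 0.539 between WT and KO and 0.628 between KO and rescue, and at 0.05, -0.021 and -0.106 with the labels' groups, where genes are not independent replicates. At least 2-fold changes numbered 731 up and 780 down in the pair named WT, 347 and 498 in that named KO and 563 and 566 in that named rescue. With the labels they numbered 895 and 1522, 1011 and 1226, and 1007 and 1034.

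Loss of Ptbp1 would be read from Ptbp2 and from exons that Ptbp1 represses. As labelled, KO against WT had Ptbp2 at -1.0 and Ptbp1 at -0.54, and neither passed. By edgeR 0 genes passed, with 29 at an unadjusted p under 0.05, and DESeq2 called 0. Genes with the largest changes missed the threshold with an adjusted p of 1. The metalloproteinase Mmp3 (4.02) and the sugar transporter Slc2a6 (3.40) were higher, with Hp at 27.68 and 0.04 CPM in the libraries labelled KO and KO_TNF and Cxcl5 at 33.64 and 0.62. Tgfbi (-5.55), Cnn1 (-3.47) and Nol3 (-3.19) were lower. Ccl2 (4.15), Icam1 (3.80) and Vcam1 (2.56) did not pass. The TNF target list had a median of 1.47 (camera adjusted p = 0.000165, adjusted p = 0.774 with an estimated correlation) with 0 members past the threshold. Cholesterol synthesis (median 0.37, camera adjusted p = 2.2e-08), DNA replication (median -0.33, camera adjusted p = 0.000165) and p53 targets (median 0.19, camera adjusted p = 0.0243) had 0 members past the threshold too, and an adjusted p = 0.774 with an estimated correlation.

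With the groups that the file names read, KO against WT (labelled Rescue and WT_TNF against labelled WT and KO) raised Ptbp2 by 2.43 ± 0.11 (adjusted p = 0.00129). Ptbp1 (0.10 ± 0.09, adjusted p = 0.409) and Ptbp3 (0.22) did not pass. Cell division genes rose throughout. Cyclins Ccnb1 (2.02 ± 0.08), Ccne2 (2.07) and Ccna2 (1.93) and the replicative helicase subunit Mcm5 (1.72) rose, as did all 30 DNA replication and mitosis genes (30 over the list alone), median 1.27 (camera adjusted p = 4.1e-18, adjusted p = 0.596 with an estimated correlation). The largest rises were those of the phosphodiesterase Pde2a (4.97), the keratinocyte envelope gene Sprr1a (4.33), Mdga1 (3.80), the water channel Aqp5 (3.70), Ifi27l2a (3.66), the cardiac transcription factor Gata4 (3.35), Cdh13 (3.21) and cardiac troponin Tnnt2 (3.15).

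The stem and endothelial cell marker Cd34 fell by 7.56 ± 0.12 (adjusted p = 0.000188), with Thy1 (-8.32), the gelatinase Mmp2 (-8.77), Mmp3 (-7.18), laminin Lama4 (-4.52) and Dcn (-3.87). Neither list of such genes passed: extracellular matrix and integrins had 7 rises and 10 falls of 29 (8 and 10 over the list alone, camera adjusted p = 0.267), and smooth muscle and fibroblast markers 1 rise and 7 falls of 21 (1 and 7 over the list alone, camera adjusted p = 0.154). For genes near 0 the levels are given: Efemp1 was at 157.80 and 99.97 CPM in the libraries named WT and 0.15 and 0 in those named KO, S1pr3 at 13.16 and 54.17 against 0.05 and 0.10, and prostacyclin synthase Ptgis at 28.91 and 35.71 against 0.05 and 0.15. Of the TNF and NF-kB targets 0 rose and 10 fell (0 and 10 over the list alone), with Icam1 at -2.92, Vcam1 at -1.97 ± 0.40 (adjusted p = 0.0214), Cxcl1 at -2.41 and Bcl3 at -3.55, median -1.06 (camera adjusted p = 8.9e-07, adjusted p = 0.596 with an estimated correlation). Ccl2 (-1.43, adjusted p = 0.0753), Tnfaip3 (-1.73), Nfkbia (-0.53) and Sele (-0.43) did not pass.

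Splicing regulators had 11 rises and 0 falls of 37 (11 and 0 over the list alone), including Mbnl1 (0.85) and Celf1 (0.62), median 0.17 (camera adjusted p = 0.00749, adjusted p = 0.596 with an estimated correlation). Of 23 p53 targets 1 rose and 8 fell (1 and 8 over the list alone), such as Perp (-3.52), Gdf15 (-1.21) and Pmaip1 (-1.13), median -0.18 (camera adjusted p = 0.0128, adjusted p = 0.596 with an estimated correlation). Cholesterol synthesis had 0 rises and 4 falls of 17 (0 and 4 over the list alone), Lss (-0.89), Cyp51 (-0.86), Insig1 (-0.81) and Fdft1 (-0.56), median -0.28 (camera adjusted p = 0.0397, adjusted p = 0.616 with an estimated correlation). Neuronal genes had 7 rises and 4 falls of 14 (7 and 5 over the list alone), with Ank3 at -1.86 and Gap43 at -3.48, and the list did not pass (camera adjusted p = 0.456). Endothelial markers had 2 rises and 4 falls of 14 (2 and 6 over the list alone), with Kdr at -2.55 and Cav1 at 0.95 (camera adjusted p = 0.0597, fry adjusted p = 0.0389, adjusted p = 0.596 with an estimated correlation). Most listed endothelial markers were near 0 CPM, Kdr among them. TNF receptor components had 1 rise and 5 falls of 26 (0 and 3 over the list alone), Ripk1 (-1.38) and Ripk3 (-0.96) among them (camera adjusted p = 0.0792). Interferon genes did not pass as a list over both treatments (0 rises and 1 fall of 34, 0 and 1 over the list alone, median 0.93, mean 0.58, camera adjusted p = 0.275), with a median of 2.34 in the untreated libraries and -0.37 in those given TNF, and Usp18 (2.47) and Ifi44 (2.64) did not pass. Shear-responsive and YAP-linked genes had 5 rises and 1 fall of 17 (5 and 1 over the list alone), with Bmp4 at 1.35 and Nqo1 at 0.69, and the list did not pass (camera adjusted p = 0.123).

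Over all genes 4204 passed (2135 up, 2069 down) by edgeR and 3605 by DESeq2. Leaving out the library labelled WT gave 2622, that labelled KO 1998, that labelled KO_TNF 1100 and that labelled Rescue_TNF 1075. The comparison is between 2 lines with 1 pair of libraries each, so differences between clones cannot be told from loss of Ptbp1.

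A human PTBP1 cDNA should restore repression by Ptbp1 and lower Ptbp2. Rescue against KO as labelled had Ptbp2 at 1.70 and Ptbp1 at -0.03, and neither passed. By edgeR 0 genes passed, with 27 at an unadjusted p under 0.05, and DESeq2 called 3. Genes with the largest changes missed the threshold with an adjusted p of 1.00. They were Sprr1a (3.37), Ifi27l2a (2.60), Tnnt2 (2.19) and the synaptotagmin Syt13 (2.16), and Thy1 (-6.24), Efemp1 (-4.96), Cd34 (-4.14) and Nynrin (-3.65). Ccl2 (-2.64), Icam1 (-3.78) and Vcam1 (-1.31) did not pass. DNA replication genes had a median of 0.77 (camera adjusted p = 5.0e-22, adjusted p = 0.817 with an estimated correlation) with 0 members past the threshold, and the TNF target list had a median of -0.69 (adjusted p = 0.157). Cholesterol synthesis (median -0.37, camera adjusted p = 9.3e-14), endothelial markers (median -0.48, camera adjusted p = 0.00121), p53 targets (median -0.17, camera adjusted p = 0.00121) and smooth muscle and fibroblast markers (median -0.30, camera adjusted p = 0.0243) had 0 members past the threshold and an adjusted p = 0.817 with an estimated correlation.

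With the groups that the file names read, Rescue against KO (labelled KO_TNF and Rescue_TNF against labelled Rescue and WT_TNF) lowered Ptbp2 by 1.51 ± 0.11 (-1.51, adjusted p = 0.00505). Ptbp1 fell too, by 1.17 ± 0.09 (-1.17, adjusted p = 0.00536), and Ptbp3 (-0.04) did not pass. Antiviral genes were lower. Oas1a (-5.69), Oas1g (-6.39) and Oas2 (-4.45), which make the activator of RNase L, fell with Usp18 (-4.52), Ifi44 (-5.57) and Slfn8 (-5.90), with reads of Oas1a and Oas1g partly shared between near copies. Of 34 interferon genes 0 rose and 13 fell (0 and 23 over the list alone), median -2.52 (camera adjusted p = 4.6e-05, adjusted p = 0.925 with an estimated correlation). Other large falls were those of Tgfbi (-7.35 ± 0.34), Cnn1 (-5.70), Krt19 (-4.57), Pmaip1 (-4.15), integrin Itga4 (-4.06) and Egfl7 (-2.43). The vasodilator peptide Adm was at 6.2 and 4.5 CPM in the libraries named KO and 0.04 and 0 in those named rescue.

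The matrix genes Mmp2 (6.14), Mmp3 (5.41), Mmp13 (3.21), Lum (6.29) and Dcn (3.21) rose in the libraries named rescue, although the matrix list had 4 rises and 5 falls of 29 (6 and 7 over the list alone) and Mmp13 turned to -0.92 without the library labelled WT_TNF. Rises were also seen in Gnpda2 (5.17), Fam49a (5.51) and the kinesin Kif1a (5.59), while Fn1 fell by 0.73. Slit3, a guidance cue, was at 0.10 and 0 CPM in the libraries named KO and 6.31 and 7.48 in those named rescue. Of the TNF and NF-kB targets 3 rose and 0 fell (1 and 0 over the list alone), Birc3 (1.55) among them, median 0.49 (camera adjusted p = 0.0014, adjusted p = 0.925 with an estimated correlation). Vcam1 (1.23, adjusted p = 0.0850), Ccl2 (1.29), Sele (1.78) and Icam1 (0.27) did not pass. DNA replication genes had 1 rise and 12 falls of 30 (1 and 16 over the list alone), with Ccnb2 at -0.95, Cdc20 at -0.81 and Ccna2 at -0.80, median -0.36 (camera adjusted p = 4.6e-05, adjusted p = 0.925 with an estimated correlation). Cholesterol synthesis had 3 rises and 1 fall of 17 (5 and 1 over the list alone), with Lss at 1.2 and Cyp51 at -0.83, median 0.35 (camera adjusted p = 0.00425, adjusted p = 0.925 with an estimated correlation). Unfolded protein response genes had 1 rise and 6 falls of 18 (1 and 9 over the list alone), with Herpud1 at -1.0, Asns at -0.78 and Dnajb9 at 0.98, median -0.29 (camera adjusted p = 0.0105, adjusted p = 0.925 with an estimated correlation).

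The other 10 lists did not pass by camera. Among them p53 targets had a median of 0.10 and a mean of -0.24 with the test pointing up (adjusted p = 0.832), and matrix genes a median of -0.03 and a mean of 0.40 with the test pointing down (adjusted p = 0.871). Ripk1 (1.48), Nova1 (2.41) and Btg2 (0.58) rose, and Tnfrsf1b (-0.78), Cyld (-0.55), Mbnl1 (-0.81), Celf1 (-0.47) and Nqo1 (-1.03) fell. Over all genes 2601 passed (1246 up, 1355 down) by edgeR and 2426 by DESeq2. Leaving out the library labelled KO_TNF or that labelled Rescue_TNF left 0 calls, with 2424 and 2275 genes at an unadjusted p under 0.05.

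Rescue against WT holds what the added cDNA did not bring back, and also any difference that is particular to the rescue line. With the labels' groups 0 genes passed by edgeR, with 91 at an unadjusted p under 0.05, and DESeq2 called 9. Nkd2 (3.95), Cfb (3.31), Ch25h (3.05), Ccl5 (2.84), Ptgis (-7.69) and Thy1 (-6.70) missed the threshold with an adjusted p of 1.00, as did Ptbp1 (-0.57), Ptbp2 (0.70), Ccl2 (1.52), Vcam1 (1.25) and Icam1 (0.02). The TNF target list had a median of 0.88 (adjusted p = 0.0817). DNA replication (median 0.46, camera adjusted p = 2.2e-08), smooth muscle and fibroblast markers (median -0.32, camera adjusted p = 0.0108) and interferon genes (median -0.34 and mean -0.40 while the test pointed up, camera adjusted p = 0.00267) had 0 members past the threshold and an adjusted p = 0.974 with an estimated correlation.

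With the groups that the file names read, Ptbp1 fell by 1.07 ± 0.09 (-1.07, adjusted p = 0.0047) and Ptbp2 rose by 0.92 ± 0.11 (adjusted p = 0.0088). Gata4 (3.69), Nkd2 (6.27), Peg3 (5.32), Olfm1 (3.45), the G protein subunit Gnai1 (2.98), adenylate cyclase Adcy1 (2.96), Itm2a (2.93) and the histone Hist1h2bc (2.99, a gene with near copies) rose. Cd34 (-8.21), Thy1 (-8.42), Perp (-6.49), Cnn1 (-6.01), Gap43 (-5.90), Lama4 (-5.81), Pmaip1 (-5.28), Krt19 (-4.43), Itga4 (-3.86), Col18a1 (-2.79), Pdgfra (-2.65) and Mmp2 (-2.63) fell. Of these, Cnn1, Krt19 and Itga4 fell by similar amounts against the libraries named KO. Their falls are hence particular to the libraries named rescue and are not changes of KO that failed to return. DNA replication genes had 28 rises and 1 fall of 30 (29 and 1 over the list alone), with Ccne2 at 1.86, Cdc6 at 1.67 and Ccnb1 at 1.51, median 0.95 (camera adjusted p = 1.5e-15, adjusted p = 0.576 with an estimated correlation). TNF targets had 0 rises and 5 falls of 36 (0 and 4 over the list alone), with Icam1 at -2.64, Cxcl1 at -1.93 and Bcl3 at -3.31, median -0.58 (camera adjusted p = 0.00501, adjusted p = 0.576 with an estimated correlation). Vcam1 (-0.75) and Ccl2 (-0.14) did not pass.

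Interferon genes had 0 rises and 3 falls of 34 (0 and 1 over the list alone), with Oasl1 at -3.16 and Cxcl9 at -3.98, median -1.81 (camera adjusted p = 0.000193, adjusted p = 0.576 with an estimated correlation). Splicing regulators had 8 rises and 1 fall of 37 (8 and 1 over the list alone), with Srsf7 at 0.46 and Srsf2 at 0.41 (camera adjusted p = 0.0332, adjusted p = 0.576 with an estimated correlation). Endothelial markers had 1 rise, Podxl (1.74), and 4 falls of 14 (1 and 4 over the list alone), with Ecscr at -6.05 and Egfl7 at -1.38 (camera adjusted p = 0.0416, fry adjusted p = 0.0397, adjusted p = 0.576 with an estimated correlation). Most listed endothelial markers were near 0, with 3 of 31 at a mean of at least 10 CPM. Of 23 p53 targets 1 rose and 6 fell (1 and 6 over the list alone, camera adjusted p = 0.0416, adjusted p = 0.576 with an estimated correlation). The median (0.009) and mean (0.014) of shear-responsive genes were above 0 while their test pointed down (adjusted p = 0.694). Over all genes 3128 passed (1588 up, 1540 down) by edgeR and 2729 by DESeq2. Leaving out the library labelled KO_TNF or that labelled Rescue_TNF left 0, with 2573 and 2722 genes at an unadjusted p under 0.05, and leaving out that labelled WT or KO left 1754 or 1165. In both Rescue comparisons, as in KO against WT, differences between clones cannot be told from effects of the added cDNA.

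Exons that Ptbp1 represses should enter messenger RNA once it is lost. With the labels' groups the weighted fit called 0 of 12519 nodes in each of the 4 comparisons, with 334 (KO against WT), 376 (Rescue against KO), 323 (Rescue against WT) and 400 (TNF) at an unadjusted p under 0.05. Without the library labelled WT_TNF it called 3, 1 and 12 nodes in the 3 genotype comparisons, and without that labelled Rescue_TNF 1 in Rescue against KO and 1 in Rescue against WT. The unweighted limma fit fixed beforehand called 0 of 28664 nodes with either grouping, with 1066 nodes at an unadjusted p under 0.05 for KO against WT with the labels and 1935 with the file names. With the groups that the file names read, the weighted fit called 129 nodes in 98 genes for KO against WT (84 up, 45 down). A 34-nt exon of Ptbp2 (chr3:119724612-119724645 in GRCm38, coding) was included at 0.562 and 0.698 in the libraries named WT, 1 and 1 in those named KO, and 0.891 and 0.942 in those named rescue (difference 0.37, adjusted p = 0.00769). A 167-nt exon of the pyruvate kinase gene Pkm (chr9:59675029-59675195 in GRCm38, coding), which Ptbp1 keeps out in dividing cells, rose by 0.196 (adjusted p = 0.00272).

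A 183-nt coding exon of Phldb2 (chr16:45774163-45774345 in GRCm38) rose by 0.881 (adjusted p = 0.00174), an alternative acceptor part of 162 nt in tropomyosin Tpm2 (chr4:43515842-43516003 in GRCm38, partly coding) by 0.758 and a 51-nt coding exon of palladin, Palld (chr8:61534858-61534908 in GRCm38), by 0.664. A 99-nt coding exon of filamin Flnc (chr6:29452799-29452897 in GRCm38) fell by 0.494, and a 129-nt, partly coding exon of the lipoprotein receptor gene Scarb1 (chr5:125281105-125281233 in GRCm38) fell by 0.561. Nodes in Dennd1a (0.714), Trip10 (0.635), Pbrm1 (0.626), Gabbr1 (0.606), Ganab (0.477), Mef2d (0.411), Rtn4 (0.368) and Dlg4 (0.34) rose, and those in Ktn1 (-0.484), Myof (-0.47), Osbpl9 (-0.454), Arhgef11 (-0.446) and Myl6 (-0.202) fell. Of the 35 genes of the list of known PTBP1 events with a tested node, 12 had a called node, 9 up and 3 down. Leaving out the library labelled Rescue left 10 calls, and leaving out that labelled WT, KO or WT_TNF left 25, 44 or 25.

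**Figure D4:**
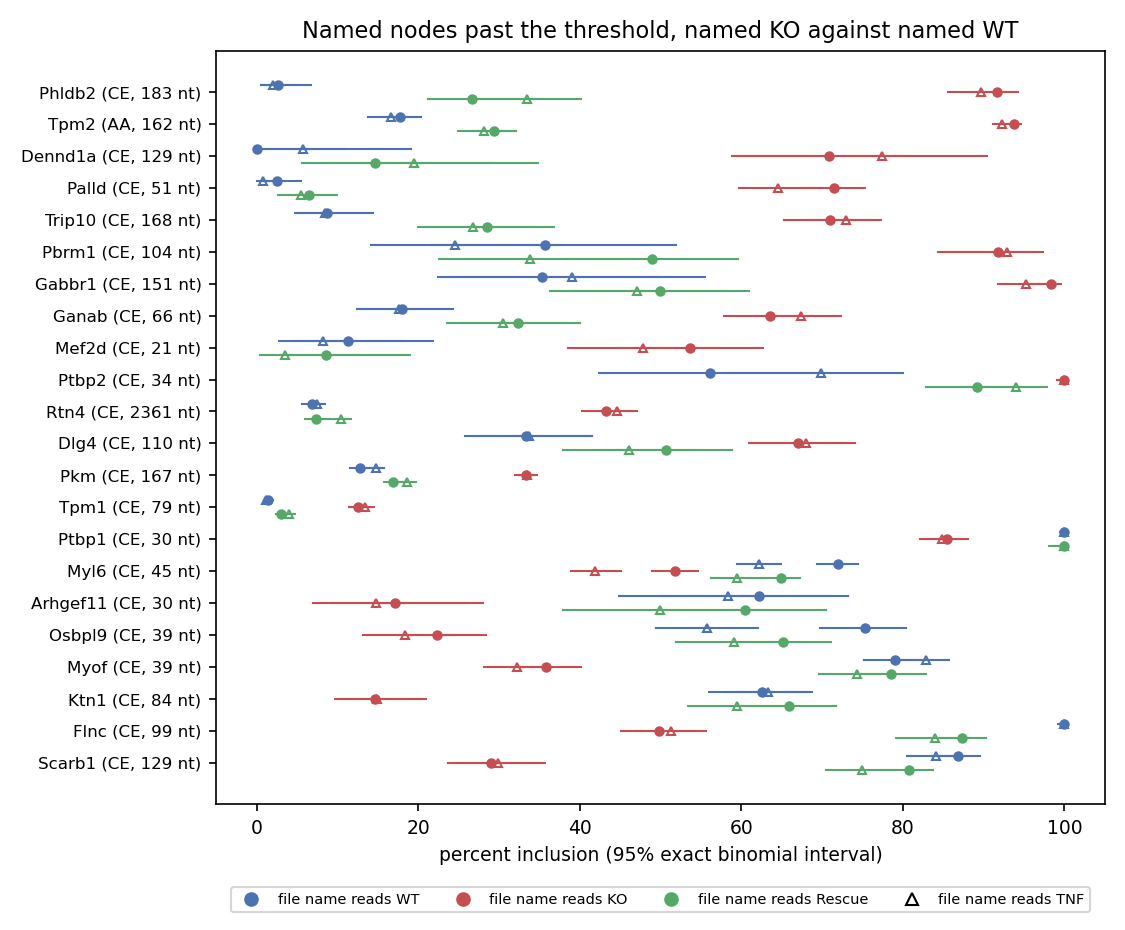
Psi of named nodes in each library; the 183-nt exon of Phldb2 changed by 0.881 and the 34-nt exon of Ptbp2 by 0.37 in KO against WT as named.

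Rescue against KO as named uses the same libraries named KO, so opposite signs for nodes called above are no evidence of a return by themselves. Phldb2 fell by 0.605, Palld by 0.62, Tpm2 by 0.642 and Pkm by 0.156, and Scarb1 (0.485) and Ktn1 (0.48) rose. In all 93 nodes in 77 genes were called (41 up, 52 down), and 11 of the 35 genes with known events had a called node (3 up, 8 down). Further nodes were in Etl4 (0.513), Ptk2b (0.459), Magi3 (-0.607), Dpf2 (-0.553) and Actn1 (-0.122). Leaving out the library labelled WT left 20 calls, that labelled KO 21, that labelled Rescue 1, that labelled WT_TNF 12, that labelled KO_TNF 13 and that labelled Rescue_TNF 37. Rescue against WT had 5 called nodes (2 up, 3 down), among them Fbln2 (-0.366), Flnc (-0.143) and Golt1b (0.133), and 0 of the 35 genes with known events. Leaving out single libraries gave 0 without that labelled WT, 10 without that labelled KO, 2 without that labelled Rescue, 2 without that labelled WT_TNF, 1 without that labelled KO_TNF and 3 without that labelled Rescue_TNF. TNF changed 0 nodes by the weighted fit, with 732 at an unadjusted p under 0.05. The weighted fit was chosen after a simulation, in which it recovered few changes of 0.2. In these data it did call smaller changes, as only 66 of the 93 nodes for Rescue against KO reached 0.2. The simulated recovery thus does not carry over to these nodes, and how many small changes were missed is not known.

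Across genes, KO minus WT in the untreated libraries was set against Rescue minus KO in those given TNF, which share no library. A slope of -1 would be a full return. Both differences still hold a library of the KO line, with opposite signs. Whatever is particular to that line hence lowers the slope without any return, so a negative slope alone is no evidence of one. With the file names' groups the slope was -0.379 (bootstrap interval -0.413 to -0.346) for genes and -0.335 (-0.363 to -0.305) for nodes, and in the other pairing -0.238 (-0.268 to -0.213) and -0.314 (-0.351 to -0.279). Nodes with at least 50 reads in all libraries had slopes of -0.467 (-0.502 to -0.429) and -0.425 (-0.474 to -0.37), and genes of at least 50 CPM had -0.471 and -0.227. As labelled, the slopes for genes were 0.659 (0.639 to 0.681) and -0.017 (-0.058 to 0.024), and those for nodes 0.078 (0.048 to 0.11) and -0.347 (-0.382 to -0.309), the latter -0.468 with at least 50 reads. The slope of 0.659 uses the same libraries as the TNF responses of the pairs named WT and rescue. It restates the correlation of 0.812 between them and is not a separate result. Genes are not independent replicates.

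Markers of the cell type were weak for an endothelial line. Eng was at 255.03 to 362.84 CPM, but Pecam1 reached at most 0.56 and Cdh5 at most 1.33. A mean of at least 1 CPM over the libraries was met by 11 of 31 endothelial markers, against 19 of 22 smooth muscle and fibroblast markers. Col1a1 was at 6368.41 to 14911.47 CPM. Cd34 was at 167.26 and 178.21 CPM in the libraries labelled WT and KO and under 1 in the others. Few blood (4 of 14) and epithelial (2 of 12) markers and under 50% of neuronal ones (11 of 25) met this mean, and Ptprc was at 0. Thy1 was at 62.55 and 35.38 CPM in the same pair and at most 0.19 in the others. Cd34 and Thy1 thus separated the libraries named WT from the other 4, while Eng and Col1a1 overlapped, and a change of cell state or a difference between clones would both produce this.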

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

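Tests in this part were chosen after the result was seen.

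CRISPR cuts of a coding exon can leave transcripts that join other exons. An unannotated junction of Ptbp1 joined chr10:79858824 to chr10:79860824 (GRCm38) and passed over 4 or 5 exons in annotated transcripts that extend past its acceptor. It made up 14.56% (11.66 to 17.85) of the reads from its donor in the libraries named KO, with 36 of 240 reads in the library labelled Rescue and 41 of 289 in that labelled WT_TNF, and 0 of 483 and 0 of 132 in those named WT and rescue, where 3 reads would be 0.62% and 2.27%. In these 3 transcripts the exons passed over hold 657, 777 and 855 nt, each with a remainder of 0 after division by 3, and 3 other transcripts end within the region.

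Some chemokines, such as Ccl5 and Cxcl10, and many interferon response genes differed in their TNF response between the pair named KO and the other pairs. Chemokines were not tested as a list. In the added model 224 genes passed (66 up, 158 down) by edgeR with 1 residual degree of freedom, against 116 with RLE factors, 112 with at least 10 counts in every library and 23 with the second quantification. In the same model 0 passed with the labels' groups, with 841 at an unadjusted p under 0.05. List medians with the labels were nonetheless lower still, at -5.72 for interferon genes and -4.57 for TNF and NF-kB targets. The values that follow are those with the file names' groups. Interferon genes had a median difference of -3.10 (-3.095), with 24 of 34 lower (32 over the list alone; camera adjusted p = 5.3e-53, adjusted p = 0.725 with an estimated correlation), among them Cxcl10 (-3.50), Ifit1 (-3.40) and Isg15 (-3.13). TNF and NF-kB targets had a median of -1.46 (-1.459), with 17 of 36 lower (28 over the list alone; camera adjusted p = 2.0e-35, adjusted p = 0.725 with an estimated correlation). The interferon genes stood high in the untreated library named KO, at a median of 2.34 over that named WT. With TNF, KO minus WT was -0.37. By these medians, most of the list's difference from the pair named WT lay in the high start. Single genes varied, as Cxcl10 also ended well below the library named WT with TNF. These medians do not cover the pair named rescue.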

How the results depend on the processing

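No paired analysis was possible beyond the additive model, which already tests TNF within genotypes, because each group had 1 library. The cause was not tested for any change below unless stated.

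With the groups that the file names read, edgeR called 2802 genes for TNF, 4204 for KO against WT, 2601 for Rescue against KO and 3128 for Rescue against WT, each against 0 with the labels, and 25 of 60 list results passed by camera against 15. TNF target medians went from 0.84 to 2.48 (WT), from -2.98 to 0.94 (KO, reversed), from 2.48 to -0.18 (KO minus WT untreated), from -1.21 to -1.71 (with TNF), from -3.46 to -1.54 (difference, KO minus WT) and from 5.18 to 1.40 (Rescue minus KO). The slopes across genes went from 0.659 to -0.379 (reversed) and from -0.017 to -0.238. The value of 0.659 is the slope between the TNF responses of the pairs named WT and rescue, so this reversal follows from the regrouping. Reversed genes were Peg3 (-1.43) for TNF, and for KO against WT Hp (-11.13), Mmp3 (-7.18), Cxcl5 (-11.39), Tgfbi (1.56), Nol3 (1.60), Vcam1 (-1.97), Icam1 (-2.92) and Ptbp2 (2.43), where the values of Hp and Cxcl5 are set by groups at 0 CPM. For Rescue against KO they were Sprr1a (-2.09), Ifi27l2a (-5.08), Tnnt2 (-1.86), Syt13 (-2.98) and Ptbp2 (-1.51), and for Rescue against WT Icam1 (-2.64).

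With the labels' groups DESeq2 called 98 genes for TNF, 3 for Rescue against KO and 9 for Rescue against WT, and 0 lists passed with an estimated correlation and 0 by fry. With the file names 0 lists passed with an estimated correlation and 3 by fry. The first slope with the labels was 0.637 with the second quantification and 0.683 with at least 10 counts in every library, and with the file names -0.42 with at least 10 counts. The 224 genes of the added model became 116 with RLE factors, 112 with at least 10 counts and 23 with the second quantification. Untransformed psi gave 3 nodes for KO against WT and 2 for Rescue against KO with the file names, and the weighted fit gave 2 for Rescue against WT at a psi difference of 0.2. Ptbp1 in the second quantification was at 219.2, 260.3, 265.0, 274.2, 82.4 and 90.1 CPM in the libraries labelled WT, KO, Rescue, WT_TNF, KO_TNF and Rescue_TNF.

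Leaving out single libraries with the file names' groups gave 3 to 3744 genes for TNF, 1075 to 4048 for KO against WT, 0 to 2716 for Rescue against KO and 0 to 4581 for Rescue against WT. Weighted node counts were 10 to 130, 1 to 37 and 0 to 10 for the genotype comparisons, and with the labels 0 to 3, 0 to 1 and 0 to 12. Without the library labelled WT_TNF, Ch25h reversed in KO against WT (2.19, range -6.28 to 2.19) and Rescue against KO (-5.13, range -5.13 to 3.33), as did Mmp13 (-0.92, range -0.92 to 3.59) and Nfkbia (-0.43, range -0.43 to 1.3) in Rescue against KO.

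Of 1992 values of named genes with the file names' groups and a library left out, 1367 kept their result, 511 lost the threshold, 110 gained it and 4 reversed. Of 1541 values under other settings 1485 kept their result. Named nodes held less well, as 121 of 280 values with a library left out kept their call and 159 lost it.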

Other observations

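Xist, the RNA that silences an X chromosome, was at 1171.35 and 986.95 CPM in the libraries labelled WT and KO, 785.69 and 686.33 in those labelled Rescue and WT_TNF, and 2007.18 and 2160.34 in those labelled KO_TNF and Rescue_TNF. Ifit1, an antiviral gene, was at 18.05 CPM in the library labelled WT and 209.73 in that labelled Rescue, neither of which was given TNF by label or by name.

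Of the tests below, those of mislabelling, those of counting noise and normalization in the slopes, and the splits with the labels' groups, apart from that by the weighted fit, were fixed before the data were examined, and the other tests were chosen after the result was seen.

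The libraries fell into pairs by file name and not by label. A mislabelled TNF treatment was tested by the median of TNF targets with the file names' groups, which was 2.03 (2.026) against 0.20 with the labels. A mislabelled genotype was tested by the lowest Ptbp2 level in the libraries named KO, which was 185.4 CPM against at most 78.8 in the others. Both values fit labels that were assigned to the wrong libraries, and the wrong order could lie in the labels or, less likely given these values, in the file names. Files of 1 sample held 1 library in both quantifications, so a swap of single gene count files is not a likely source. The psi and junction files were not matched to them.

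TNF targets rose less in the libraries named KO. Normalization would have had to bring the difference near 0, but the highest of 4 medians under other settings was -1.41 (-1.407). Levels already high before TNF would show in the untreated libraries, where KO minus WT was -0.178. The slope over the genes that rose was 0.271 against 0.558 over those that fell, which does not exclude a weaker exposure to TNF, because equal scaling was assumed and interferon genes started high. The median response of the libraries named rescue minus that of those named KO was 1.31 (1.314). This restates the smaller response that defined the pattern, so it cannot tell whether loss of Ptbp1 is the source. A difference between clones could give the same smaller response as loss of Ptbp1, because each line is 1 pair of libraries.

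Ptbp1 junctions differed between the libraries named KO and those named rescue. Depth does not account for it, as 19.2 reads of the unannotated junction would have been met in those named rescue at the share of those named KO, and 0 were seen. The annotated junction from chr10:79859712 to chr10:79859781 (GRCm38) had 25.04% of the summed reads of itself and its upstream neighbour in those named KO. Its share was 60.95% in those named WT and 0 of 145 in those named rescue (Fisher's exact p = 2.1e-16 for rescue against KO). This junction was picked for having no reads in some libraries, so the test restates that difference. Unedited cells mixed into those named KO would need a share of 21.4%. Cd34, Efemp1 and Nynrin, chosen as high in those named WT and near 0 in those named rescue, were at a median of 0.52% of the level in those named WT. This does not exclude such a mixture, because it assumes that unedited cells kept these genes at the level of the libraries named WT. The libraries named rescue may come from other edited cells than those named KO, but these values do not decide it.

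For Ptbp1 being lower in the libraries named rescue, skipping of its 34-nt exon (chr10:79862014-79862047 in GRCm38) was 24.35% there against 9.68% in those named WT (Fisher's exact p = 0.000121). In those named KO it was 3.55% (2.04 to 5.7), with a Fisher's exact p of 6.1e-11 for rescue against KO. By library the shares were 14.74% (9.58 to 21.3) and 6.02% (3.24 to 10.07) in those labelled WT and KO, and 28.81% (17.76 to 42.08) and 19.64% (10.23 to 32.43) in those labelled KO_TNF and Rescue_TNF, so the intervals of that labelled WT and the rescue libraries overlapped.

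For the gene slopes, the shallower was -0.227 over genes of at least 50 CPM and -0.238 under other factors or the second quantification, and the unannotated junction had a Fisher's exact p of 2.2e-08, which left the question open. Slopes were shallower for genes than for nodes in 1 of 2 pairings with at least 20 reads per node. They were shallower in both with at least 50 (-0.467 and -0.425 for nodes), but in 1 of 2 again if genes were kept to at least 50 CPM.

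With 10 splits of the libraries the splits are too few for a share under 0.05. For TNF with the labels, 10 of 10 splits had as many genes as the real 0 (highest other 0) and 10 of 10 as many nodes by the unweighted fit (real 0, highest other 0), with a highest other of 13 by the weighted fit (real 0). With the file names 1 of 10 had as many genes as the real 2802 (highest other 0), and 10 of 10 as many nodes by the weighted fit as the real 0 (highest other 10).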
